A study of Rattus norvegicus with 45 samples.

How the data were processed

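Gene counts from 3' Tag-seq, a method that sequences a tag near the 3' end of each transcript, were analysed for 45 libraries of rat medial preoptic area on postnatal day 10. Per the labels, the dams received corn oil, 50 µg/kg bisphenol A (BPA), or a mixture of equal parts BPA, bisphenol S (BPS) and bisphenol F (BPF) at 50 or 150 µg/kg from gestation until birth. The 8 groups of exposure and sex held 5 or 6 libraries each, from 24 litters with 6 litters per exposure. A litter gave at most 1 library of each sex, and 21 litters gave both. The litter was read from the library name. The labels state that dams were assigned as pairs sharing a cage but not which litters shared one, so p-values over litters leave a shared cage out of account.

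RNA was extracted from frozen tissue with a kit made for fixed tissue, per the labels' protocols. Cutadapt 1.18, STAR 2.7.3a, SAMtools 1.10, bedtools 2.27.1 and the rat build mRatBN7.2 are named in the submitters' processing notes. Their settings, the annotation, the strand setting of the counting and any removal of duplicate reads are not given in the sources used here. The deposited values are raw whole-number counts per gene, 1 table per sex, and both tables are marked as having had outlying libraries removed before deposit. All 45 count columns were matched to a library by name, and 0 columns were left unmatched. Totals ran from 4397460 to 7223180 counts per female library and from 4747461 to 6740045 per male library. No coordinates were used. Of 40643 gene identifiers, 35203 matched a symbol in a RefSeq gene table of the later assembly GRCr8, 179 matched only a synonym, and 14468 carried no assigned symbol. With no strand setting stated, reads of overlapping and antisense genes cannot be told apart, and pseudogene copies can share reads with their parent gene.

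Counts were tested in R 4.3.3 with edgeR 4.0.16: genes with low counts were removed by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and robust quasi-likelihood F-tests were adjusted by Benjamini-Hochberg with a threshold of 0.05. The tests covered 18354 genes in females, 18426 in males and 19026 in the fit of both sexes. Within each sex the 4 exposure groups shared 1 fit. Each exposure was compared with corn oil, and the exposures with each other at equal total dose (50 µg/kg BPA against 50 µg/kg mixture) and equal BPA dose (50 µg/kg BPA against 150 µg/kg mixture). Slopes on the dam's licking/grooming and on nest attendance over postnatal days 1 to 5 were fitted per 1 SD of the measure over the libraries of a sex, with exposure in the model, and the 3 differences between an exposure's slope and the corn oil slope were tested jointly. The labels give no unit for either care measure. Co-expression with Esrrg was the slope of each other gene on log2 CPM of Esrrg (prior count 2), per 1 SD, with exposure in the model. Sex, and the difference of each exposure's effect between sexes, were tested over all 45 libraries.

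The 28 gene lists (13 of pathways, 15 of cell type and region markers, 8 to 75 genes each) were written before the data were examined, as were the groups, the tests, the alternatives marked as planned and the rule for named genes. Of their 643 genes, 638 were in the tables. Lists with at least 5 tested members, 27 in every comparison, were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01, adjusted over the lists of 1 comparison. Camera with the correlation estimated per list, and fry, were the alternatives. A count "adjusted over the list alone" repeats the edgeR adjustment over the members of 1 list. Another 4 lists (motile cilia, long neuronal genes, cytosolic ribosomal proteins, mitochondrial-encoded proteins) were written after the data had been seen and were adjusted among themselves.

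Genes were named by rule. For each exposure against oil, each care slope and the exposure by licking/grooming interaction, these were up to 10 genes per direction past the threshold, or, with fewer than 5 past it, those plus the 3 with the lowest p in each direction (6 in all for the interaction), given as values. Other comparisons named up to 3 per direction past the threshold, and each list up to 4 members past it, lowest p first. Esrrg was always given, and the sex-linked genes in the sex comparisons. Identifiers without an assigned symbol were counted but not named, and some genes that the rule names are not reported here.

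Maternal care was compared between exposures over litters with two-sided exact permutation tests of means. Relations of Esrrg with care and with region markers were given as Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples, or exact permutation within a group, using Python 3.11.15, scipy 1.17.1 and numpy 2.4.6. Figures were drawn with matplotlib 3.10.9.

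Alternatives were DESeq2 1.42.0 with its own size factors and filter, RLE scaling, no filter, the replicate number or the litter as a block, voom with library quality weights, fits of only the groups compared, care as covariates, the first principal component of the marker genes as a covariate, and leaving out each library in turn. For the effects between sexes, leaving out the library of each sex lowest in long neuronal genes, and the rRNA and mitochondrial-encoded percent as covariates for that list, were added after the data had been seen. For each comparison of groups, 40 splits of the same libraries into groups of the same sizes were drawn (60 for the comparisons of sex), the real one included. The edgeR step was tested on simulated data with 200 changed genes. For BPA against oil in females, run on 18147 genes, it recovered 13.4% of genes changed 1.25-fold, 55.2% of those changed 1.5-fold and 71.2% of those changed 2-fold. For the same comparison in males, run on 18257 genes, it recovered 23.9%, 55.2% and 80.3%. For the difference of the BPA effect between sexes, run on 18821 genes, it recovered 1.5%, 35.8% and 60.6%. The series title also names the DNA methylome, for which the tables used here hold no values.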

Results

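Messenger RNA of the medial preoptic area, a hypothalamic region that takes part in sexual and parental behaviour, was measured in 22 female and 23 male rat pups on postnatal day 10. The series asked whether prenatal exposure to bisphenols changed gene expression, and whether maternal care after birth moderated the effect, with Esrrg and its co-expressed genes named in its title. Esrrg encodes estrogen-related receptor gamma, an orphan nuclear receptor that binds BPA. Corn oil was given to the dams of 5 female and 6 male libraries, 50 µg/kg BPA to those of 6 and 5, the mixture at 50 µg/kg to those of 6 and 6, and the mixture at 150 µg/kg to those of 5 and 6. The dams' bisphenol treatment is named below by compound and dose. Library totals ranged from 4397460 to 7223180 counts in females and from 4747461 to 6740045 in males. Between 419 and 1079 of these counts per library belonged to Esrrg. Intervals below cover the spread between libraries, and reads without molecular identifiers are not independent molecules.

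The sex of the pups set the clearest difference. Xist, the transcript that silences the inactive X, was 42.4-fold higher in females (log2 difference 5.41 ± 0.12 SE, n = 22 and 23, adjusted p = 4.05e-31). The X-linked genes Eif2s3, a translation initiation factor, and Kdm6a, a histone demethylase, both of which escape X inactivation, were higher in females by 0.61 ± 0.04 and 0.40 ± 0.05. The Y-linked genes Eif2s3y, Uty and Kdm5d were lower in females by log2 differences of -6.96, -3.91 and -4.12, with adjusted p of 1.73e-41, 1.03e-40 and 8.76e-39. Reads listed under Usp9y did not separate the sexes (-0.04 ± 0.16, adjusted p = 0.985). In all, 18 genes passed the threshold, 10 higher and 8 lower in females, 4 of them without an assigned symbol. For Esrrg the difference between the sexes was -0.003 ± 0.069.

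Esrrg, as a count scaled by library size (CPM), had group means from 121 to 148. In females it was 139.5 ± 17.7 CPM after corn oil (SD, n = 5), 129 ± 11.4 after BPA (n = 6), 130.3 ± 15.4 after the 50 µg/kg mixture (n = 6) and 137 ± 31.7 after the 150 µg/kg mixture (n = 5). In males it was 121 ± 19.6 after corn oil (n = 6), 148 ± 21.7 after BPA (n = 5), 123 ± 22.4 after the 50 µg/kg mixture (n = 6) and 146 ± 29.6 after the 150 µg/kg mixture (n = 6). The largest of these differences from oil, in BPA males, was 0.29 ± 0.15 on the log2 scale (95% interval -0.02 to 0.59, edgeR adjusted p = 0.471), with 5 of 5 libraries above the oil mean and 2 of 5 above every oil library. In males of the 150 µg/kg mixture it was 0.26 ± 0.14 (interval -0.03 to 0.56, adjusted p = 0.992), with 5 of 6 libraries above the oil mean. In females the interval ran from -0.36 to 0.13 for BPA, from -0.35 to 0.15 for the lower mixture dose and from -0.28 to 0.23 for the higher. Whether the BPA effect on Esrrg differed between sexes was tested directly. The female effect minus the male effect was -0.40 ± 0.20 (95% interval -0.80 to -0.002, edgeR unadjusted p = 0.0491, adjusted p = 0.698 over all genes). For the mixture at 50 and 150 µg/kg the same differences were -0.12 and -0.29. The unadjusted p does not allow for the other comparisons in which Esrrg was tested.

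**Figure D1:**
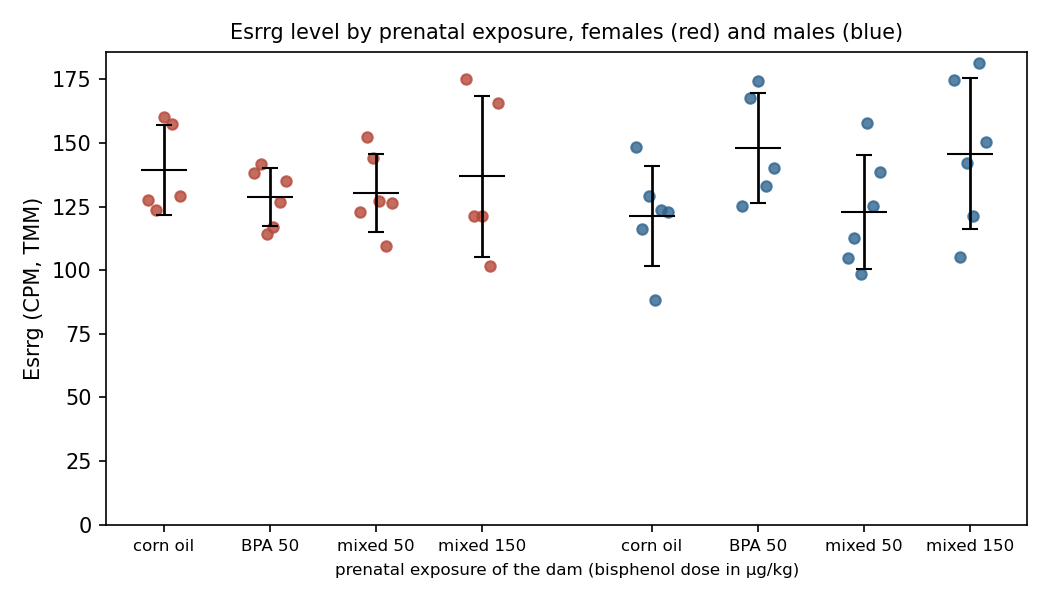
Esrrg level in CPM for each library (points), by prenatal exposure, in females (red) and males (blue), with the group mean and SD in black. Group means lie between 121 and 148 CPM, and the groups overlap.

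In BPA females, the genes with the lowest p included Tp73, a transcription factor of the p53 family that takes part in multiciliated cell formation, and Cimap1b, a ciliary microtubule protein. Tp73 was 1.96-fold the oil level (log2 difference 0.97 ± 0.22 SE) and Cimap1b 5.01-fold (2.33 ± 0.59), each above every oil library in 6 of 6 libraries. B9d1, a protein of the ciliary transition zone, was 1.22-fold (0.28 ± 0.07), also in 6 of 6. The lowest p among lower genes belonged to Kirrel2 (-1.15 ± 0.32), Pnma2 (-0.66 ± 0.19) and Slc7a14 (-0.28 ± 0.08), each below the oil mean in 6 of 6 libraries. All 6 had an edgeR adjusted p of 1, and 0 genes passed the threshold in this comparison, with 667 at an unadjusted p under 0.05 where chance gives 918. DESeq2 and voom with quality weights also called 0. Fitted on the BPA and oil libraries alone, edgeR called 1 gene, Pnma2.

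After the 50 µg/kg mixture, females had Tmem203, a membrane protein of the endoplasmic reticulum, above the oil level by a log2 difference of 0.58 ± 0.13, Nit2, an amidase, at 1.27-fold (0.35 ± 0.08) and Fkbp10, a collagen chaperone, at 1.54-fold (0.62 ± 0.15). Kcnmb2, a subunit of calcium-activated potassium channels, had a log2 difference of -0.32 ± 0.08, and the synaptic adhesion protein Tenm3 at 0.826-fold (-0.28 ± 0.07) and Dennd1b at 0.832-fold (-0.27 ± 0.07). For each of these, 6 of 6 libraries lay on that side of the oil mean, and each had an adjusted p of 0.971. After the 150 µg/kg mixture, Zfhx4, a homeobox transcription factor, was at 1.33-fold (0.41 ± 0.09, 5 of 5 libraries), Cchcr1 at 1.95-fold (0.97 ± 0.27, 5 of 5) and the pseudogene Rps15-ps12 at 2.32-fold (1.22 ± 0.34, 4 of 5). Psmb8, a subunit of the immunoproteasome, was at 0.524-fold (-0.93 ± 0.24), Gmfb at 0.586-fold (-0.77 ± 0.22) and the pseudogene Ddx21-ps3 at 0.329-fold (-1.61 ± 0.44), each in 5 of 5 and all 6 with an adjusted p of 1. With edgeR, DESeq2 and voom with quality weights alike, 0 genes passed at either dose, and edgeR gave 891 and 565 genes at an unadjusted p under 0.05.

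In BPA males, Robo2, an axon guidance receptor, was at 744 ± 71.8 CPM against 550.1 ± 72.5 after oil (SD, n = 5 and 6), 1.35-fold (log2 difference 0.44 ± 0.09 SE, adjusted p = 0.325), above every oil library in 5 of 5 libraries. Schip1, a protein of the axon initial segment and node of Ranvier, was at 1.37-fold (0.45 ± 0.10) and Lmbr1 at 1.22-fold (0.29 ± 0.06). Hid1, which takes part in the making of dense-core vesicles, was at 0.687-fold (-0.54 ± 0.12), the heme A synthase Cox15 at 0.796-fold (-0.33 ± 0.08) and Rtbdn at 0.747-fold (-0.42 ± 0.10). All 6 lay on the same side of the oil mean in 5 of 5 libraries, with an adjusted p of 0.325. Here edgeR called 0 genes but had 2089 at an unadjusted p under 0.05 (1089 higher, 1000 lower) where chance gives 921. DESeq2 called 9, of which 7 were higher, among them Robo2, while voom with quality weights called 0.

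In males of the 50 µg/kg mixture, Ly75, an endocytic receptor of immune cells, was at 1.31-fold the oil level (0.39 ± 0.10), Tmem161b at 1.26-fold (0.33 ± 0.09) and the copper-dependent ferroxidase Heph at 1.34-fold (0.43 ± 0.12). Reads listed under Usp9y were at 0.524-fold (-0.93 ± 0.25), although they did not separate the sexes. Abhd14a was at 0.680-fold (-0.56 ± 0.16). In males of the 150 µg/kg mixture, the biotin-recycling enzyme Btd was at 1.39-fold (0.48 ± 0.12), Tmbim1 at 1.22-fold (0.29 ± 0.08) and the actin-binding protein Cald1 at 1.24-fold (0.31 ± 0.09). Mak, a kinase that limits cilium length, had a log2 difference of -0.82 ± 0.19, with the lysosomal mannosidase Man2b2 at 0.718-fold (-0.48 ± 0.12) and C2cd4c at 0.719-fold (-0.48 ± 0.12). Each of these 11 values held its direction against the oil mean in 6 of 6 libraries, with adjusted p of 1 at the lower and 0.992 at the higher dose. All 3 tools called 0 genes at both doses, and edgeR gave 639 and 753 at an unadjusted p under 0.05.

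BPA and the mixtures were compared at equal total dose and at equal BPA dose. BPA, BPS and BPF share a pair of phenol rings and differ in the bridge between them. Robo2 was lower after the 50 µg/kg mixture than after 50 µg/kg BPA in males by a log2 difference of -0.29 ± 0.09 (95% interval -0.47 to -0.11, adjusted p = 0.331), and lower after the 150 µg/kg mixture by -0.32 ± 0.09 (-0.49 to -0.14, adjusted p = 0.967). In females, Tp73 differed by -0.51 ± 0.19 (-0.90 to -0.11, adjusted p = 1) at equal total dose and by -0.48 ± 0.21 (-0.90 to -0.06, adjusted p = 1) at equal BPA dose, while Cimap1b differed by -0.05 (-0.88 to 0.79) and -0.13 (-1.04 to 0.77). Robo2, Tp73 and Cimap1b were named for their low p for BPA against oil, from the same BPA libraries. That choice alone favours lower values in any other group, so these intervals are not independent of it. For Esrrg the mixture minus BPA was 0.02 (-0.22 to 0.25) and 0.09 (-0.16 to 0.34) in females, and -0.27 (-0.57 to 0.04) and -0.02 (-0.33 to 0.28) in males. No gene passed the threshold with edgeR or DESeq2 in any of these 4 comparisons or in the 2 comparisons of the mixture doses. At equal total dose, 773 genes in females and 2276 in males had an unadjusted edgeR p under 0.05, at equal BPA dose 417 and 792, and between mixture doses 866 and 520. At equal total dose the interval of the difference lay within 1.5-fold either way for 77.3% of genes in females and 70.2% in males, and at equal BPA dose for 75.6% and 73.9%.

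Among the gene lists, BPA males had 11 of 75 tested genes of oxidative phosphorylation and 2 of 23 of cholesterol synthesis above the oil level, the others below it, with medians of -0.07 and -0.12. These were camera calls (adjusted p = 4.57e-06 and 0.00018) that were lost with the correlation estimated from the data (adjusted p = 0.638 with an estimated correlation for both). Of region markers in the same libraries, Pde10a was at 636 ± 178 CPM after BPA against 380.3 ± 123 after oil (SD, n = 5 and 6) and Lhx8 at 21.5 ± 14.1 against 39.7 ± 9.29. Isl1, of the same marker list as Pde10a, was at 70.7 against 70.8. None of these passed the threshold, nor did the difference of 0.93 in the first principal component of the markers (exact permutation p = 0.0714, adjusted p = 0.428). Members of the oxidative phosphorylation and cholesterol lists also fell with Esrrg, as given below. Of nuclear receptors, Rora, Nr3c1 and Nr3c2 passed in BPA males when adjusted over the list alone, against 0 over all genes. Thyroid hormone genes Slco1c1, Dio2 and Slc16a10, which carry or activate the hormone, were higher and Itih3 lower when adjusted over the list alone, again with 0 over all genes. In males of the 50 µg/kg mixture, 12 of 13 endothelial markers and 6 of 6 red blood cell markers were above oil (medians 0.13 and 0.54, camera adjusted p = 8.36e-05 and 1.25e-05, adjusted p = 0.221 and 0.226 with an estimated correlation). In males of the 150 µg/kg mixture, 13 of 14 pericyte and fibroblast markers were above oil (median 0.32, camera adjusted p = 9.46e-05, adjusted p = 0.513 with an estimated correlation). In females, 9 of 44 synaptic genes were above oil after BPA and 8 of 44 after the 150 µg/kg mixture (medians -0.06 and -0.04, camera adjusted p = 0.00529 and 0.00185, adjusted p = 0.653 and 0.458 with an estimated correlation). At equal total dose in males, the glutamate receptor genes Grin2c, Gria3, Grin2b and Grm5 were lower after the mixture when adjusted over the list alone, with 0 of 29 over all genes. Of these lists, no camera call in any exposure, care, sex or interaction comparison held with an estimated correlation.

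Maternal care differed between exposures by less than the spread between litters. Licking/grooming over 6 litters each was 344 ± 144 after oil (SD), 362 ± 106 after BPA, 297 ± 120.0 after the lower and 310.3 ± 122 after the higher mixture dose, in units that the labels do not state. Nest attendance was 1669 ± 389.7 after oil, 1670.0 ± 436 after BPA and 1564 ± 487 and 1502 ± 284.5 after the lower and higher mixture dose. Exact two-sided permutation tests against oil gave p from 0.463 to 1.0 over the 6 comparisons, with adjusted p of at least 0.961. Licking/grooming and nest attendance were related over 24 litters with r = 0.286 (permutation p = 0.178) and rho = 0.271 (p = 0.199).

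Slopes on the care measures had 0 genes past the threshold in either sex. In males the lowest p on licking/grooming belonged to Slit1, a ligand of Robo receptors, with a log2 slope of 0.14 ± 0.03 per SD of care (SE, n = 23), followed by Usp29 (0.07 ± 0.02) and Nckap5 (0.10 ± 0.03), and on the negative side by the myosin light chain Myl6 (-0.07 ± 0.02), the brain creatine kinase Ckb (-0.08 ± 0.02) and the growth factor Mdk (-0.12 ± 0.03), all with an adjusted p of 1. In females these were the ciliary gene Iqcc (0.27 ± 0.06, n = 22), Pkd1l1 (0.18 ± 0.05), Wdr90 (0.15 ± 0.04), the glycosylation enzyme Pmm2 (-0.16 ± 0.04), Lrriq3 (-0.34 ± 0.08) and the Hsp90 cochaperone Cdc37 (-0.13 ± 0.03), also with an adjusted p of 1. On nest attendance, female values were Dhx37 0.28 ± 0.06, the neurotrophic factor Artn 0.49 ± 0.12, the immediate early gene Ier2 0.28 ± 0.07, Zfp623 -0.23 ± 0.06, Cd200l2 -0.30 ± 0.09 and the glycine receptor Glra3 -0.21 ± 0.06 (adjusted p of 1). Male values were Xist 0.50 ± 0.11 (adjusted p = 0.915), Lyve1 0.38 ± 0.11, the pseudogene Ppid-ps7 0.14 ± 0.04, the glucose transporter Slc2a1 -0.12 ± 0.03, Pigx -0.11 ± 0.03 and Alg1 -0.17 ± 0.05. One male library after oil had more Xist reads than the others, with 17.4 CPM against at most 4.90 in that group. It came from litter 49, whose dam had the highest nest attendance after oil (2434, next 1645), and without it the slope of Xist was 0.23. At an unadjusted p under 0.05, edgeR gave 506 genes in females and 820 in males for licking/grooming, and 581 and 422 for nest attendance. DESeq2 called 0 for 3 of these 4 slopes and 2 for licking/grooming in males, Myl6 and Usp29, and voom with quality weights called 0 for all 4.

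Whether care moderated the exposure effect was tested as a difference of slopes. In females, the genes with the lowest p for licking/grooming were Lama2, a laminin chain, Tgfbi, a secreted matrix protein, Ddr2, a collagen receptor, Cped1, Fam174b and Etl4. Per SD of licking/grooming, the slope of Lama2 exceeded the oil slope by 0.47 ± 0.14 after the 50 µg/kg mixture, and differed by -0.37 ± 0.15 after BPA and -0.46 ± 0.14 after the 150 µg/kg mixture. Ddr2 differed by 0.63 ± 0.17, -0.13 ± 0.18 and -0.41 ± 0.17 in the same order, Cped1 by 0.50 ± 0.17, -0.31 ± 0.18 and -0.57 ± 0.17, and Tgfbi by 1.67 ± 0.28, 0.33 ± 0.30 and 0.34 ± 0.25. Fam174b differed by 0.24 ± 0.06, -0.16 ± 0.07 and -0.15 ± 0.06, and Etl4 by 0.20 ± 0.07, -0.04 ± 0.07 and -0.24 ± 0.07. All 6 had an edgeR adjusted p of 0.179, 0 genes passed, and 1159 had an unadjusted p under 0.05 where chance gives 918. DESeq2 called 17, including Lama2, and voom with quality weights called 1, Ranbp3l. The edgeR count was 7 without replicate 1 of the 150 µg/kg mixture females, and 12 with no filter on low counts. Pericyte and fibroblast markers varied too. From the lowest to the highest licking/grooming library their mean went from 3.90 to 3.92 log2 CPM after oil and 4.44 to 3.75 after BPA. After the 50 µg/kg mixture it went from 2.91 to 3.93, and after the 150 µg/kg mixture from 4.31 to 2.95. Libraries between were not in order. A differing share of these cells between punches was not tested and cannot be told apart from moderation by care. For Esrrg in females, the slope differences were 0.07 ± 0.09, -0.04 ± 0.10 and -0.30 ± 0.09. The joint edgeR test gave an unadjusted p of 0.00622 and an adjusted p of 0.675 over all genes. That unadjusted p does not allow for the other comparisons in which Esrrg was tested.

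In males the lowest p belonged to Ttpa, a vitamin E transfer protein, whose slope on licking/grooming exceeded the oil slope by 0.66 ± 0.22 after BPA, 0.54 ± 0.17 after the lower and 0.85 ± 0.17 after the higher mixture dose. Nme5, a ciliary gene, and Cfap20dc differed most after the 150 µg/kg mixture, by 0.69 ± 0.15 and 0.38 ± 0.09. Slc22a25 differed by -0.58 ± 0.17, -0.14 ± 0.14 and -0.58 ± 0.13, and the transcription factor Etv1 by 0.20 ± 0.09, -0.18 ± 0.07 and 0.10 ± 0.07. Esrrg differed by -0.35 ± 0.17, 0.05 ± 0.13 and -0.22 ± 0.13. All 6 had an adjusted p of 0.926. With edgeR, DESeq2 and voom with quality weights 0 genes passed, and 877 had an unadjusted edgeR p under 0.05. Precursor markers of oligodendrocytes, Pdgfra, Cspg4, Sox10 and Olig1, passed when adjusted over the list alone, with 0 of 10 over all genes. For nest attendance, edgeR called 0 genes in either sex, with 553 and 356 at an unadjusted p under 0.05 in females and males, and DESeq2 called 0 and 1, the latter being Mobp, a myelin protein.

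Esrrg itself showed no relation to care that passed a permutation test. Over 22 females r was -0.088 with licking/grooming (rho = -0.159, permutation p = 0.696 and 0.478) and -0.167 with nest attendance (rho = -0.202, p = 0.457 and 0.367). Over 23 males r was 0.092 (rho = -0.127, p = 0.676 and 0.561) and 0.03 (rho = -0.005, p = 0.891 and 0.984). Each sex had 4 relations, with and without group means removed, and the smallest adjusted p of Pearson's r was 0.696 in females and 0.891 in males. Without the 2 libraries farthest from the median of care, r was -0.022 and -0.075 in females and 0.026 and 0.001 in males. Within groups of 6 libraries, r ranged from -0.681 to 0.611 in females and from -0.448 to 0.547 in males, with exact permutation p of at least 0.157 and adjusted p of at least 0.389 for r. The lowest exact permutation p of rho was 0.103, for licking/grooming in males of the 150 µg/kg mixture (rho = -0.771, adjusted p = 0.617). Groups of 5 libraries had no such test, among them females of the 150 µg/kg mixture. In those females the edgeR slope of Esrrg on licking/grooming differed from the oil slope by -0.30 ± 0.09, as given above. The edgeR slope of Esrrg per SD was -0.02 ± 0.05 on licking/grooming and -0.04 ± 0.05 on nest attendance in females, and 0.004 ± 0.058 and 0.03 ± 0.05 in males.

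Many genes followed the level of Esrrg across libraries of the same exposure. In females 1580 of 18353 tested genes passed, 808 rising and 772 falling with Esrrg. In males 4259 of 18425 passed, 2046 rising and 2213 falling, and 182 and 554 of the passing genes carried no assigned symbol. One SD of Esrrg was 0.20 log2 CPM in females and 0.28 in males. The genes nearest to Esrrg in females were Adamtsl1, a secreted matrix protein (slope 0.34 ± 0.03 log2 per SD, adjusted p = 1.06e-06), the synaptic vesicle protein Sv2c (0.39 ± 0.04, adjusted p = 1.89e-05) and the NMDA receptor subunit Grin2a (0.18 ± 0.02, adjusted p = 1.89e-05), and on the falling side the transcription factors Klf6 (-0.33 ± 0.04) and Pou3f2 (-0.31 ± 0.04) and Ubfd1 (-0.19 ± 0.03). In males they were the serotonin receptor Htr4 (0.40 ± 0.03, adjusted p = 6.32e-10), the sarcoglycan Sgcz (0.35 ± 0.03, adjusted p = 6.32e-10) and the collagen Col11a1 (0.29 ± 0.03, adjusted p = 1.15e-08), against Ndrg2 (-0.27 ± 0.03, adjusted p = 1.32e-08), Fam131c (-0.35 ± 0.04) and the tubulin Tubb4b (-0.21 ± 0.02).

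Region markers moved with Esrrg in opposite directions. Of 13 markers of striatum and other basal forebrain, 8 rose in females (10 rose and 2 fell when adjusted over the list alone), and in males 10 rose and 2 fell (11 and 2). They included the phosphodiesterase Pde10a (0.30 ± 0.08 in females, 0.48 ± 0.08 in males), the dopamine receptor Drd1 (0.33 ± 0.08 and 0.56 ± 0.10) and the striatal regulator Rgs9 (0.31 ± 0.05 and 0.42 ± 0.06). The adenosine receptor Adora2a rose in males by 0.66 ± 0.11. Of 11 markers of preoptic area and anterior hypothalamus, 3 fell in females (5 over the list alone), and in males 5 fell and 1 rose. Among these, Nkx2-1, a patterning factor of the ventral forebrain, fell by 0.44 ± 0.08 and 0.46 ± 0.12, Lhx8 by 0.52 ± 0.14 and 0.54 ± 0.13, and the calcitonin receptor Calcr in males by 0.55 ± 0.08. The preoptic list in females was the 1 camera call that held with an estimated correlation (adjusted p = 0.000594, and adjusted p = 0.0253 with an estimated correlation). For the striatal list the adjusted p with an estimated correlation was 0.217 in females and 0.108 in males, and for the preoptic list in males 0.203.

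**Figure D2:**
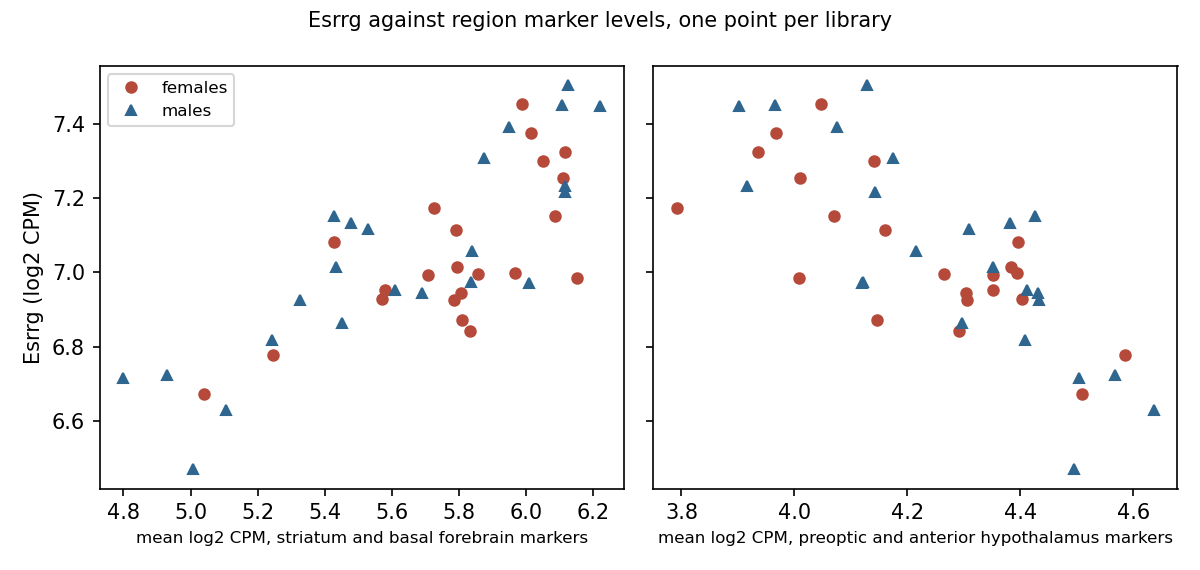
Esrrg (log2 CPM) in each of 22 female (circles) and 23 male (triangles) libraries against the mean log2 CPM of striatum and basal forebrain markers (left) and of preoptic and anterior hypothalamus markers (right). Esrrg is higher where striatal markers are higher and lower where preoptic markers are higher.

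As means over each list, Esrrg correlated with striatal markers with r = 0.683 in females (rho = 0.583, permutation p = 0.00043 and 0.00509, adjusted p = 0.000469 and 0.00509) and 0.848 in males (rho = 0.843, permutation p = 1e-05, the smallest that the resampling can give, and 2e-05). With preoptic markers r was -0.74 in females (rho = -0.673, permutation p = 0.00011 and 0.00075, adjusted p = 0.000147 and 0.001) and -0.804 in males (rho = -0.8, permutation p = 1e-05 and 4e-05). These belonged to 12 relations. Leaving out the 2 libraries farthest from the median of the markers gave r of 0.504 and 0.832 for striatal and -0.743 and -0.793 for preoptic markers. With group means removed, r was 0.705 and 0.845, and -0.792 and -0.766.

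Members of other lists passed too, as 1580 of 18353 genes in females and 4259 of 18425 in males did, and none of these lists passed with an estimated correlation. Glutamate transmission genes rose with it in 11 of 29 cases and fell in 3 in females, and rose in 13 and fell in 8 in males, with the AMPA receptor subunit Gria2 at 0.22 ± 0.03 and Grin2a at 0.25 ± 0.03 in males (adjusted p = 0.297 and 0.322 with an estimated correlation). Cholesterol synthesis fell with Esrrg in 9 of 23 genes in females and 13 of 23 in males, including the mevalonate kinase Mvk at -0.23 ± 0.04 and -0.24 ± 0.05 (adjusted p = 0.12 and 0.108 with an estimated correlation). Of 75 genes of oxidative phosphorylation, 1 fell in females and 29 in males, such as cytochrome c, Cycs, at -0.145 ± 0.029 (adjusted p = 0.735 and 0.336 with an estimated correlation). Oligodendrocyte precursor markers fell in 1 of 10 cases in females and 8 of 10 in males, among them Olig2 at -0.31 ± 0.06 and Gpr17 at -0.32 ± 0.06 (adjusted p = 0.269 and 0.108 with an estimated correlation). Astrocyte markers fell in 2 of 15 cases in females and 6 of 15 in males, with Aldoc at -0.14 ± 0.03 and -0.27 ± 0.04 (adjusted p = 0.911 and 0.206 with an estimated correlation). Markers of myelinating oligodendrocytes rose in 1 of 13 cases in females, Cldn11 at 0.32 ± 0.09, and fell in 7 of 14 in males, with Mag at -0.44 ± 0.09 (adjusted p = 0.846 and 0.294 with an estimated correlation). Pericyte and fibroblast markers rose in 4 of 14 cases in females, with Igf2 at 0.43 ± 0.11 and Col1a1 at 0.38 ± 0.11 (adjusted p = 0.269 with an estimated correlation). In males no member of this list was among the genes named as past the threshold. Immediate early genes rose in 3 of 24 cases and fell in 1 in females, and rose in 10 and fell in 2 of 25 in males, with Egr3 at 0.30 ± 0.05 and 0.56 ± 0.09 (adjusted p = 0.269 and 0.406 with an estimated correlation). Of nuclear receptors, 4 of 38 rose in females, and in males 6 rose and 5 fell, with the mineralocorticoid receptor Nr3c2 at 0.19 ± 0.03 and 0.20 ± 0.03 (adjusted p = 0.272 and 0.4 with an estimated correlation).

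**Figure D3:**
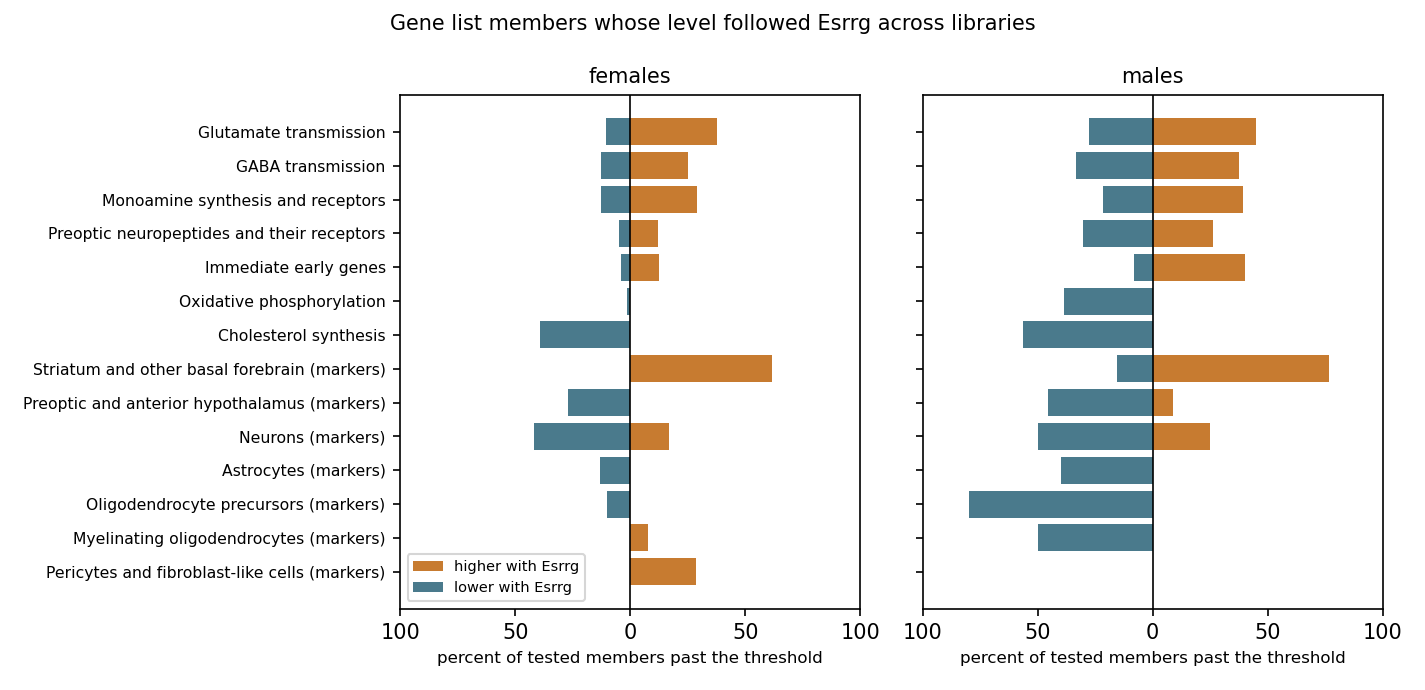
Percent of the tested members of 14 gene lists whose level rose (orange, right) or fell (blue, left) with Esrrg past the threshold, in females and males. Striatal markers rise in 8 of 13 cases in females and 10 of 13 in males.

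The first principal component of the marker genes shared 55% of the variance of Esrrg in females and 73.3% in males. With this component in the model, 11 genes passed in females, among them Stac, Adamtsl1, Grin2a and Sv2c, and 0 in males, where edgeR had called 4259 without it. Other genes of like level and spread called as many genes as Esrrg in 12 of 40 draws in females and 14 of 40 in males. The count for Esrrg co-expression in females was 606 without replicate 4 of the 150 µg/kg mixture and 892 without replicate 5 of the 50 µg/kg mixture.

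Across sexes, 0 genes passed with edgeR or DESeq2 for a difference in the effect of BPA or of the mixture at either dose, with 1354, 912 and 722 genes at an unadjusted edgeR p under 0.05 where chance gives 951. For BPA the smallest adjusted p was 0.0893, and voom with quality weights called 1 gene, Lmbr1, as did the edgeR test without replicate 3 of the BPA males. For both mixture doses voom with quality weights called 0. This fit treats the 45 libraries as independent although 21 litters gave both sexes. With the litter as a random block (limma), Lmbr1 alone passed for BPA, with 1725 genes at an unadjusted p under 0.05, and with the litter as a fixed block edgeR called 0, with 1674.

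**Figure D4:**
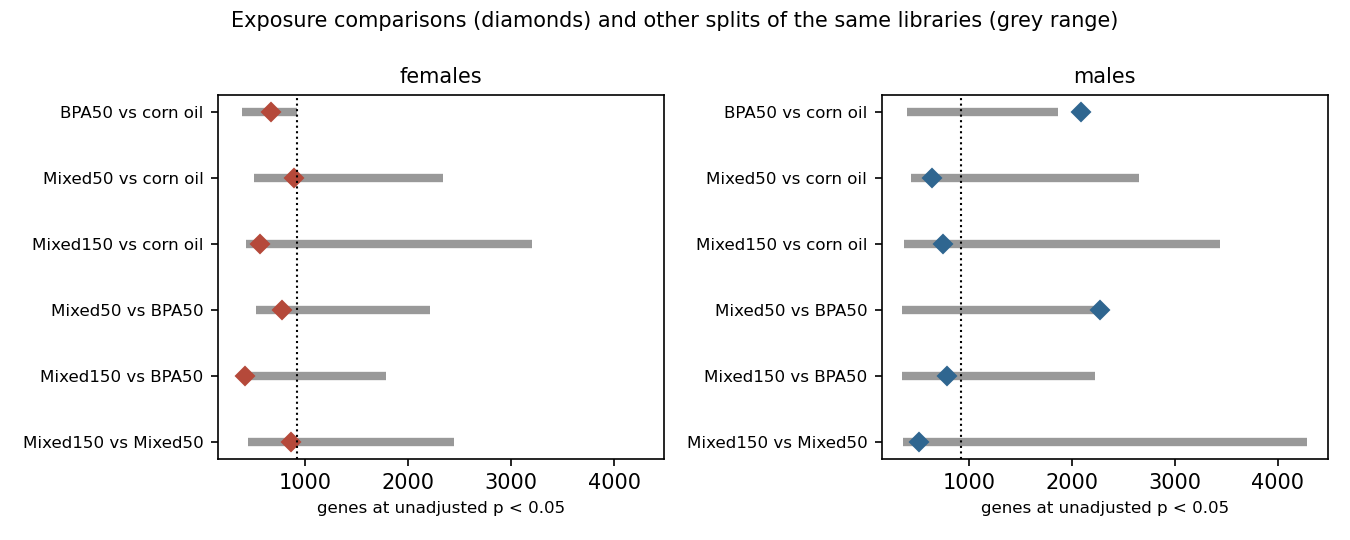
Number of genes at an unadjusted p under 0.05 (horizontal axis) in each comparison of exposures (diamonds) and the range over the other splits of the same libraries (grey bars), with the number that chance gives as a dotted line. Among males, 50 µg/kg BPA against oil had 2089 genes and the 50 µg/kg mixture against BPA 2276, above the other splits.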

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

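The splits of the libraries and the draws of other genes were chosen in advance. Tests with the marker component outside co-expression, with the long neuronal genes and with library size were chosen only after the result was seen. So were all tests of the motile cilia genes and the 4 added lists. For the marker component in co-expression, how its outcome would be read was set only after the result was seen.

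Esrrg level was followed by 1580 genes in females and 4259 in males. The tables argue against uneven recovery of long transcripts, since with the mean of 48 long neuronal genes in the model 1919 and 3913 genes passed. They also argue against a count particular to Esrrg, since 12 of 40 genes of like level and spread in females and 14 of 40 in males called at least as many, up to 3183 and 5424, and the calls of a drawn gene followed its correlation with the marker component (rho = 0.872 and 0.976). A candidate explanation is a differing mix of brain regions and cell types between tissue punches: with the marker component in the model 11 genes passed in females and 0 in males (edgeR, with 1351 and 1016 at an unadjusted p under 0.05), as the median size of the slopes of the called genes went from 0.144 to 0.066 (median SE 0.035 to 0.046) and from 0.155 to 0.053 (0.037 to 0.064). What stays open is regulation by Esrrg itself, which was not tested, because Esrrg shared 55% and 73.3% of its variance with the component.

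In BPA males, 2089 genes had an unadjusted p under 0.05 against corn oil, where chance gives 921, with 0 past the edgeR threshold and 9 past that of DESeq2. Among 40 splits, 1, the real one, gave as many (highest other 1865). That is the lowest share that 40 splits can give, and it was not adjusted for the number of comparisons screened. Chance is therefore not excluded for this count. With the marker component in the model the count was 1232, so a differing mix of tissue between punches may account for part or all of the excess. The component itself was 0.93 higher in BPA males than after oil (0.62 ± 0.76 against -0.31 ± 0.72, SD, n = 5 and 6, exact permutation p = 0.0714, adjusted p = 0.428). Library size stays open, with an exact permutation p of 0.641 for the total counts, and it cannot be told apart from the exposure by that test, since the groups' totals overlap but their means are not equal. Uneven recovery of long transcripts and RNA quality stay open as well, and neither was tested for this count. The mean of the long neuronal genes was 9.19 ± 0.04 log2 CPM in BPA males and 9.02 ± 0.13 after oil (SD). Within groups of males that mean had a correlation of -0.594 with the rRNA percent and -0.666 with the mitochondrial-encoded percent. An effect of BPA stays open too, because the design names the exposure. The count of 1232 cannot decide this, since no splits were drawn with the component in the model. Without the component, other splits gave 404 to 1865 genes.

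Motile cilia genes such as Cimap1b, Ak7, Dnah5 and Cfap65 were higher in BPA females than after oil in 19 of 19 tested cases, with a median log2 difference of 1.355 and 10 past the threshold adjusted over the list alone, against 0 over all genes. Chance stays open: 4 of 462 splits reached the difference of list means, 1.023 (highest other 1.163), but the list was written after this comparison was seen and holds Cimap1b, and its adjusted p was 0.0535 with an estimated correlation. The tables argue against choroid plexus in the punch, whose 5 tested genes had a median of -0.126, against the 2 libraries with choroid plexus transcripts (median 1.459 without them), and against library size, which the cilia genes followed within groups with a correlation of 0.4 while the BPA libraries were the smaller. What stays open is a differing share of ventricle wall with its ciliated ependyma, since 5 of the 20 genes also stand in the ependyma list, and an effect of BPA on these cells, neither of which was tested apart from the other.

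For the other comparisons, chance can be excluded for sex (1 of 60 splits, 18 genes past the threshold, highest other 1). For the 50 µg/kg mixture against BPA in males, 1 of 40 splits, the real one, gave as many (2276 genes at an unadjusted p under 0.05, highest other 2252). With the marker component in the model this count was 1134, where chance gives 921. For the BPA effect between sexes 2 of 60 splits gave as many (1354 genes, highest other 1452). These shares were not adjusted for the number of comparisons screened, so chance is not excluded for either. Nor can it be excluded elsewhere. In females as many genes came from 12 of 40 splits for BPA against oil (667, highest other 923), 22 for the 50 µg/kg mixture (891, 2335), 30 for the 150 µg/kg mixture (565, 3208), 18 and 39 for the lower and higher mixture dose against BPA (773, 2212 and 417, 1791) and 21 between mixture doses (866, 2445). In males they came from 25 splits for the 50 µg/kg mixture (639, 2651), 19 for the 150 µg/kg mixture (753, 3436), 15 for the higher mixture dose against BPA (792, 2221) and 26 between mixture doses (520, 4286), and between sexes from 28 and 26 of 60 splits for the lower and higher mixture dose (912, 3011 and 722, 4240). Splits that gave several times the real count point to a structure of the samples other than the exposure.

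Long neuronal genes differed between sexes in their contrast with oil after BPA and after the 50 µg/kg mixture. For BPA, 23 of 48 had a lower effect in females when adjusted over the list alone, with 0 over all genes (median -0.291, adjusted p = 0.0257 with an estimated correlation). For the 50 µg/kg mixture these were 12, with 0 of 48 positive (median -0.268, adjusted p = 0.00645 with an estimated correlation). For the 150 µg/kg mixture they were 0 (median -0.184, adjusted p = 0.0693 with an estimated correlation). These contrasts share the same oil groups, so they are not independent of each other. The mean of the long neuronal genes after oil was the highest of the female groups (9.17 ± 0.05 log2 CPM, SD). In males it was the lowest after oil (9.02 ± 0.13). A difference between the oil groups thus cannot be told apart from a response to the exposures. Motile cilia genes had a higher effect of the 150 µg/kg mixture in females than in males, in 12 of 19 cases when adjusted over the list alone and 0 over all genes (median 1.852, adjusted p = 0.0249 with an estimated correlation). This contrast uses the same oil females as the BPA comparison after which the cilia list was written. Their mean was the lowest of all groups (1.43 ± 0.44 log2 CPM, SD), so the value is not independent of that comparison. Without the library of each sex lowest in long neuronal genes, Mixed50_Female replicate 6 (mean 8.674 log2 CPM, group mean 8.98) and CornOil_Male replicate 6 (8.794, group mean 9.02), the medians of the long neuronal genes were -0.253 for BPA and -0.172 for the 50 µg/kg mixture, with 18 and 0 past the threshold over the list alone (adjusted p = 0.00726 and 0.0138 with an estimated correlation). Within groups their mean had a correlation of -0.594 with the rRNA percent and -0.666 with the mitochondrial-encoded percent in males, and of -0.202 and -0.244 in females. With the ribosomal protein percent it was -0.344 in males and -0.647 in females. With the rRNA and mitochondrial-encoded percents in the model the medians were -0.232 for BPA and -0.236 for the 50 µg/kg mixture, with 11 and 15 past the threshold over the list alone (adjusted p = 0.0203 and 0.00619 with an estimated correlation). The ribosomal protein percent was not in that model. The list was written after the data had been seen, and RNA quality stays open.

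Single libraries stood apart from their group by a gap that is a large share of the group's range, in 10 of 118 groups tested, where chance gives 5.9. Ttr, the transthyretin gene that choroid plexus expresses strongly, was at 181 CPM in BPA50_Female replicate 5 (next 3.02, gap share 0.984), 179 in CornOil_Female replicate 3 (next 0.699, share 0.997), 1.71 in Mixed150_Female replicate 1 (next 0.658, share 0.794) and 2.16 in Mixed50_Male replicate 1 (next 0.732, share 0.863). Xist was at 17.4 CPM in CornOil_Male replicate 2 (next 4.90, share 0.853). Nest attendance was 2434 for the dam of corn oil litter 49 (next 1645, share 0.737), the litter of that same library. At the low end stood B9d1 at 26.0 CPM in CornOil_Female replicate 3 (next 27.5, share 0.783), Tmem203 at 6.90 in Mixed50_Female replicate 4 (next 8.96, share 0.771) and Man2b2 at 22.6 in CornOil_Male replicate 1 (next 29.3, share 0.672). Zfhx4 was at 61.3 in Mixed150_Female replicate 2 (next 47.8, share 0.724).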

How the results depend on the processing

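The marker component outside co-expression, the long neuronal and motile cilia covariates, and leaving out the libraries with Ttr or Xist reads or those lowest in long neuronal genes were tests chosen only after the result was seen.

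Called values of named genes kept their direction and their side of the threshold in 157 of 160 cases under RLE scaling, 156 of 160 under DESeq2, 141 of 160 with no filter on low counts, 144 of 154 with the replicate block, 148 of 154 with the long neuronal genes in the model, 86 of 86 without the male library with Xist reads and 3540 of 3744 when 1 library was left out, the others being weaker. Without the libraries with Ttr reads 51 of 68 did so and 17 were weaker. With the marker component, 3 of 154 did so, 123 were weaker and 28 reversed. The sex difference kept its count within 1.5 times, at 17 with the litter as a fixed block, 26 with no filter, 18 without the library of each sex lowest in long neuronal genes and 18 or 19 when 1 library was left out. Replicate numbers do not pair the libraries: residual profiles with the same number had a mean correlation of -0.004 in females and -0.012 in males. With this replicate block, 1588 and 3775 genes followed Esrrg in females and males and edgeR called 0 genes for each exposure comparison.

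Esrrg co-expression in females fell to 11 genes and in males to 0 with the marker component (edgeR, 1351 and 1016 at an unadjusted p under 0.05), which shared 55% and 73.3% of the variance of Esrrg. Beyond this the cause was not tested. Without the libraries with Ttr reads it was 1028 in females, from fewer libraries. Leaving out 1 library gave 606 to 2042 in females, with 606 without Mixed150_Female replicate 4 and 892 without Mixed50_Female replicate 5, and 3500 to 4606 in males. The slopes that reversed with the marker component, none of them past the threshold then, were in females Homer1 -0.0017, Me1 0.0134, Col1a2 -0.0165 and Lhx8 0.0023. In males they were Rorb 0.0365, Hsd17b12 0.0081, Gabrq 0.0026, Adra1a 0.0012, Tet3 -0.0099, Tet2 -0.0061, Cycs 0.0374, Atp5pf 0.0047, Rcan2 0.0386, Gpx3 0.0908, Txn1 0.0214, Sod1 0.0122, Cyp51 0.0087, Cnp 0.0042, Mag 0.1933, Olig2 0.0329, Gpr17 0.0333, Aldoc 0.0035, Agt 0.0343, Tcf7l2 0.1044, Lhx8 0.2483, Nkx2-1 0.295, Pou3f2 0.1005 and Scgn 0.0605.

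Counts of 0 with edgeR became 1 in these cases, of which the cause was not tested: BPA females fitted with oil alone (Pnma2), the higher against the lower mixture dose in females without Mixed50_Female replicate 3 (Nit2, range 0 to 1), nest attendance in males with the marker component (a gene without an assigned symbol), and the BPA effect between sexes (Lmbr1) with voom and quality weights, with the litter as a random block and without BPA50_Male replicate 3 (range 0 to 1). For the exposure by licking/grooming interaction in females, DESeq2 called 17 genes, the fit with no filter 12, voom with quality weights 1 (Ranbp3l), and leaving out 1 library gave 0 to 7, with 7 without Mixed150_Female replicate 1 (Col5a1, Ranbp3l, Lama2, Ror1, Cped1, Ddr2 and Thbd). DESeq2 called 9 genes for BPA males (Robo2, Hid1, Schip1, Lmbr1, Rora, Ap3d1, Frmd4b, Nr3c1 and Ntm), 2 for licking/grooming in males (Myl6 and Usp29) and 1 for the exposure by nest attendance interaction in males (Mobp), and the cause was not tested. Camera with the preset correlation made 112 list calls, and with the estimated correlation, which allows for correlated members by construction, 1. Fry made 28, of which 13 were for Esrrg co-expression in females and 15 for that in males.

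Some differences in care changed sign without passing the test. Nest attendance after BPA minus oil was -42.55 over litters with a female library and -94.45 over those with a male library, and ran from -94.45 to 153.7 when 1 litter was left out. The other ranges were -26.5 to 59.4 for licking/grooming after BPA, -92.24 to -6.33 and -78.58 to 10.41 after the lower and higher mixture dose, and -271.5 to 48.34 and -257.5 to -14.39 for nest attendance after the lower and higher mixture dose. Correlations of Esrrg with care, pooled and with group means removed, ran from -0.238 to 0.128 and -0.233 to 0.137 for licking/grooming in females, -0.268 to -0.074 and -0.284 to -0.101 for nest attendance in females, -0.109 to 0.179 and -0.211 to 0.158 for licking/grooming in males and -0.081 to 0.118 and -0.124 to 0.178 for nest attendance in males. With group means removed and the 2 farthest libraries left out, the male values were -0.064 and -0.116.

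The precision limits what could be seen. The median 95% interval of an exposure comparison reached from 0.243 to 0.266 on the log2 scale to either side, and for 70.2% to 77.3% of genes it lay within 1.5-fold either way.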

Other observations

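The 4 added lists and their tests were chosen only after the result was seen.

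Single genes of the peptide, monoamine and GABA lists rose or fell with Esrrg, while none of these lists passed with an estimated correlation (adjusted p = 0.534 and 0.96 for peptides, 0.269 and 0.322 for monoamines, 0.967 and 0.848 for GABA in females and males). The opioid receptor Oprd1 rose by 0.22 ± 0.06 log2 per SD of Esrrg in females and 0.55 ± 0.09 in males (SE, n = 22 and 23), the neuropeptide Npy by 0.25 ± 0.05 and 0.33 ± 0.05, and the kappa opioid receptor Oprk1 in males by 0.42 ± 0.06, whereas the prolactin receptor Prlr fell by 0.24 ± 0.06 and 0.34 ± 0.07. Of these peptide genes, 5 of 42 rose and 2 fell in females, and in males 12 of 46 rose and 14 fell. The dopamine receptor Drd3 rose by 0.33 ± 0.06 and 0.76 ± 0.11, among 7 of 24 rising and 3 falling monoamine genes in females and 9 of 23 rising and 5 falling in males. The GABA-synthesizing enzyme Gad2 rose by 0.21 ± 0.03 in males, while the GABA receptor subunit Gabrq fell in males by 0.48 ± 0.08. In all, 6 of 24 GABA genes rose and 3 fell in females, and 9 rose and 8 fell in males. The thyroid hormone-binding protein Crym rose by 0.29 ± 0.08 and 0.45 ± 0.09.

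Hypothalamic peptide genes Crh and Trh fell with Esrrg in males, by 0.53 ± 0.13 and 0.21 ± 0.07. Of 12 neuron markers, 2 rose and 5 fell in females, and 3 rose and 6 fell in males (adjusted p = 0.269 and 0.4 with an estimated correlation). Tubb3 fell by 0.17 ± 0.03 and 0.22 ± 0.03 and Stmn2 by 0.16 ± 0.02 and 0.18 ± 0.03, while Rbfox3 rose in males by 0.15 ± 0.03. The cortical factor Tbr1 fell in males by 0.61 ± 0.10, and Bcl11b, which cortex and striatum share, rose by 0.10 ± 0.03 in females and 0.34 ± 0.05 in males. The estrogen-metabolizing enzyme Cyp1b1 rose in females by 0.51 ± 0.10, and the metallothionein Mt1 in males by 0.40 ± 0.07.

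Cilia genes stood at a mean of 1.43 ± 0.44 log2 CPM after oil in females (SD, n = 5), 2.45 ± 0.46 after BPA (n = 6), 1.86 ± 0.72 after the lower (n = 6) and 2.38 ± 0.71 after the higher mixture dose (n = 5). In males they stood at 2.13 ± 0.64 after oil, 1.80 ± 0.32 after the lower and 1.69 ± 0.39 after the higher mixture dose (n = 6 each), and after BPA 11 of 17 were above oil (median 0.08). After the 150 µg/kg mixture 19 of 19 were above oil in females (median 1.301, adjusted p = 0.0787 with an estimated correlation), and in males 2 of 17 (median -0.64, adjusted p = 0.216 with an estimated correlation). Long neuronal genes were below oil in 48 of 48 cases in females of the 50 µg/kg mixture, 22 of them when adjusted over the list alone and 0 over all genes (median -0.184, adjusted p = 0.0155 with an estimated correlation). In BPA males 41 of 48 were above oil, 19 of them when adjusted over the list alone and 0 over all genes (median 0.182, adjusted p = 0.102 with an estimated correlation), led by Ntm and Fgf14. Ribosomal protein genes were above oil in 71 of 74 cases in BPA females (median 0.066, adjusted p = 0.155 with an estimated correlation) and in 7 of 74 in males of the 150 µg/kg mixture (median -0.041, adjusted p = 0.216). Mitochondrial-encoded genes were above oil in 0 of 13 cases in BPA males (median -0.133, fry adjusted p = 0.365) and in 12 of 13 in females of the 50 µg/kg mixture (median 0.054, fry adjusted p = 0.331).

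Littermates of opposite sex had a mean correlation of residual profiles of 0.117 over 21 litters, against -0.005 between libraries of different litters.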
